A study of Sus scrofa with 6 samples.

How the data were processed

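Methylated DNA immunoprecipitation sequencing (MeDIP-seq) enriches sheared genomic DNA with an antibody against methylated cytosine and sequences what was pulled down. It was applied to longissimus dorsi, the long muscle of the back, from female purebred Yorkshire and Wannanhua pigs, with 3 libraries per breed. Per the labels' protocols the DNA was sonicated, ligated to adapters and enriched with a magnetic immunoprecipitation kit. The labels number the samples of each breed but do not say in words that each came from a different animal, so p-values measure only the spread between these samples, which may be technical.

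The authors deposited 1 list of peaks per library, so peaks were called separately in each library and not on pooled samples. Per the file headers peaks were called with MACS, and 5 of the 6 headers name version 1.4.2. Per the file headers all 6 runs had no control file, a p cutoff of 1e-05, a band width of 300 bp, a model fold of 10 to 30, at most 1 tag kept per position, a regional background window of 10000 bp, a tag size of 50 bp and an effective genome size of 2.60e+09. The aligner and the genome build are not given in the sources used here. For each peak the deposited lists give a count of tags, which is a whole number that was not normalized. They also give a fold enrichment, which is the ratio of tags to the local background as computed by the authors' peak caller. The deposited score of a peak is a multiple of the negative log10 of its p, as this version of the caller writes it, under a broken column heading. Fold and score are the authors' own values and were used to describe, rank or filter peaks. Some of these uses run across lists. Named regions were ranked by score averaged over libraries, and the stricter score was 1 cutoff for all libraries. The median fold of each library was also compared between breeds and set against fragment length. Without a control library, the background of every peak came from the enriched library itself, so copy number and mappability are not corrected for.

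Each list has 65536 lines and 65516 peaks, and stops part-way through a chromosome at a point that differs between libraries. Chromosomes 1, 10, 11, 12 and 13 are complete in all 6 lists, and every comparison was made on these 5 chromosomes, which span 764 Mb up to the last peak. Peaks elsewhere were left out of the comparisons. Peaks ran past the last gene of the Sscrofa11.1 gene table on 11 of the 12 chromosomes listed, so the coordinates appear to belong to another build. Chromosome lengths were not compared. Coordinates are therefore given as in the lists, no peak was assigned to a gene, exon or intron, and 15 gene lists fixed beforehand were not tested.

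Depth was read from the headers. The libraries had 10455414 to 28580061 tags, of which 6728444 to 17108367 remained after duplicates were removed. The smallest peak held 7 to 13 tags depending on the library, so a peak with few tags carries a large counting error, and a region without a peak is one that did not reach the caller's cutoff at that depth, not one without tags.

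Peaks of the 6 libraries that overlapped by at least 1 bp were merged into regions. A region was called present in a breed only if it had a peak in all 3 libraries of that breed and in none of the other. That count was set against the other ways to part the 6 libraries 3 against 3, which make 10 splits in all. Values with 1 number per library were compared by two-sided exact permutation tests, which cannot give a p below 0.1 with 3 against 3. Correlations across the 6 libraries have exact permutation p-values over 720 orders. Benjamini-Hochberg adjustment was made over 10 library measures, over the 5 chromosome shares and over 4 correlations.

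Tag counts were summed per library over the peaks of each region that was called in all 6 libraries, and tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test with robust estimation, TMM scaling, filterByExpr and a Benjamini-Hochberg threshold of 0.05. The filter removed 0 of the 19161 regions. A sum of tags over called peaks moves with the length that was called. Called lengths are therefore given beside some of the folds, and folds per kb of called peak for each set of named regions. DESeq2 1.42.0 was an alternative. Positions, overlaps and exact tests were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9.

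The groups, the exact tests, the count of regions in a single breed, the similarity of libraries, their alternatives and the rule for named regions were fixed before the data were examined. For peak lists that plan held no test of tags. The test of tags in regions called in all 6 libraries, with the plan's settings for counts, was chosen after the lists had been seen, as were the distance to chromosome ends and the length of called peaks. The rule for names took the 10 features per direction with the highest mean score among regions in a single breed, and the 10 with the largest fold change among regions that passed the test of tags with all libraries of one breed above all of the other. Its condition that a feature has a gene could not be met, so regions are named by position.

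The test of tags was tested on simulated data with the real regions, means and library sizes: among 19161 regions it recovered 45 of 100 planted 2-fold changes and 92 of 100 planted 3-fold changes, with 10 false calls among 147. Simulated regions varied independently, and libraries differed otherwise only in size. False calls from shifts that many regions share, as with fragment length or depth, are therefore not measured by it. The merging and the count of regions in a single breed recovered 200 of 200 planted regions. These were planted past the last real peak of chromosome 1, in shifted copies of the Yorkshire 1 list. Nothing there could overlap them, so this checks the counting only, not the merging of real peaks that differ in width and depth. Alternatives were other scalings, other filters and thresholds, DESeq2, a replicate block, each library left out in turn, other overlaps, equal numbers of peaks per library, a minimum width and a stricter score. Added after the lists had been seen were fragment length as a covariate, called length as an offset, whole-library tags as library size, peaks cut to 250 bp on each side of the summit, the part of chromosome 14 that every list reaches, and the removal of Yorkshire 3 and Wannanhua 1 together.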

Results

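DNA methylation was profiled by MeDIP-seq in the longissimus dorsi muscle of 2 pig breeds, the lean Western breed Yorkshire and the Chinese breed Wannanhua, with 3 libraries each. The design asks where methylation-enriched regions differ between the breeds. After removal of duplicate tags Yorkshire 1, 2 and 3 had 10600292, 15275918 and 6728444 tags, and Wannanhua 1, 2 and 3 had 7413391, 17108367 and 15377451. The fragment length that the peak caller estimated was 150, 169 and 97 bp in Yorkshire 1, 2 and 3, and 179, 193 and 202 bp in Wannanhua 1, 2 and 3. All Wannanhua values lie above all Yorkshire values, although Yorkshire 2 and Wannanhua 1 differ by only 10 bp, and 57.7% of the variance of fragment length lay between the breeds. With so few libraries, no range of fragment length held enough of both breeds for a comparison within it.

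In both breeds peaks were densest on chromosome 12 and sparsest on chromosome 13. Chromosome 12 had 105 ± 11.7 peaks per Mb in Yorkshire and 95.2 ± 20.8 in Wannanhua (SD, n = 3), and chromosome 13 had 61.4 ± 8.44 and 52.9 ± 14.3. Chromosome 10 had 91.9 ± 13.6 and 82.5 ± 20.4, chromosome 11 had 78.4 ± 10.1 and 69.5 ± 16.9, and chromosome 1 had 64.2 ± 8.36 and 55.6 ± 15.6. The density ratio of chromosome 12 to chromosome 13 lay between 1.63 and 1.97 in the 6 libraries. Peaks were also denser within 20 Mb of a chromosome end than further inside, by 1.48 ± 0.067 times in Yorkshire and 1.60 ± 0.12 times in Wannanhua. In the mean of all 6 libraries the densest 1 Mb window was chromosome 11 from 75000001 to 76000000, with 146 ± 17.2 peaks in Yorkshire and 134 ± 33.3 in Wannanhua, where chromosome 13 from 35000001 to 36000000 had slightly more (136 ± 27.6). The sparsest was chromosome 1 from 296000001 to 297000000, with 8.67 ± 1.53 and 6.0 ± 2.0 peaks.

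No breed difference in this distribution was detectable, though with 3 against 3 no exact p could be below 0.1. The share of a library's peaks on each of the 5 chromosomes gave two-sided exact permutation p-values from 0.2 to 0.6 (n = 3 per breed, adjusted p 0.6 for each), and the end-to-interior ratio gave an exact p of 0.3. Spearman's rho of peak counts across 762 windows was 0.945 to 0.984 in the 15 pairs of libraries. Windows are not independent replicates.

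**Figure D1:**
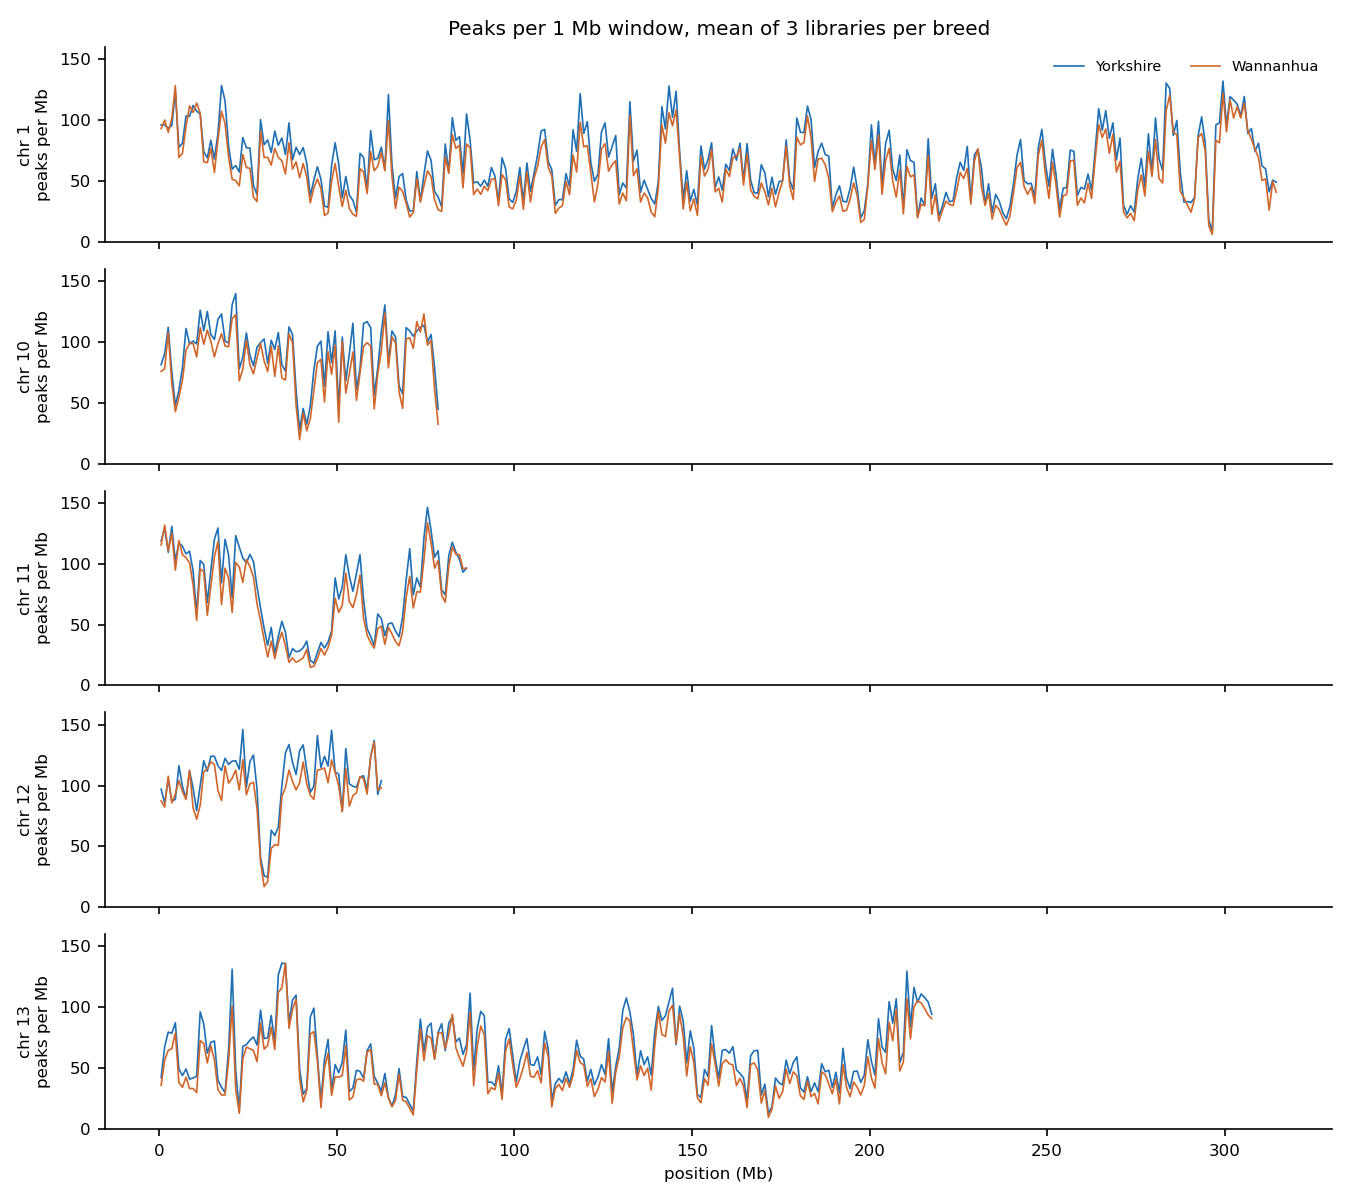
Peaks per 1 Mb window (vertical axis, peaks per Mb) against position (horizontal axis, Mb) on chromosomes 1, 10, 11, 12 and 13. Each line is the mean of 3 libraries of a breed. Both lines rise and fall together, and the window on chromosome 11 at 75 to 76 Mb is the highest in the mean of all 6 libraries.

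Yorkshire libraries had 54492 ± 7132 peaks on the 5 chromosomes and Wannanhua libraries 47775 ± 12472 (SD, n = 3; exact permutation p = 0.6, two-sided). The median peak was 424 ± 109 bp wide in Yorkshire and 565 ± 65.8 bp in Wannanhua (n = 3; exact p = 0.2). Peaks covered 26.8 ± 11.3 Mb in Yorkshire and 32.9 ± 11.7 Mb in Wannanhua (n = 3; exact p = 0.5). They held 11.3 ± 0.61% of the filtered tags in Yorkshire and 10.7 ± 1.60% in Wannanhua (n = 3; exact p = 0.8). As counts scaled to library size (CPM of filtered tags), a peak held on average 2.08 ± 0.22 in Yorkshire and 2.30 ± 0.31 in Wannanhua. The difference in median width, 141 bp, was larger than the SD of either breed, but it was 82.0 bp without Yorkshire 3, its test did not separate the breeds, and with 3 against 3 no exact p could be below 0.1. The lowest adjusted p over 10 library measures was 0.6. The fewer peaks of Wannanhua rest on Wannanhua 1, the breed's shallowest library: without it Wannanhua had 422 peaks more per library. With peaks of at least 400 bp Wannanhua had 11127 more.

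Across the 6 libraries, covered length rose with filtered tags (Pearson's r = 0.993, exact permutation p = 0.00139, adjusted p 0.00556; Spearman's rho = 1, exact p = 0.00278). Median width rose with fragment length (r = 0.979, exact p = 0.00417, adjusted p 0.00833; rho = 0.943, exact p = 0.0167). Without the 2 libraries farthest from the median of each x axis, r was 0.986 and 0.892. Median fold enrichment fell with fragment length (r = -0.947, exact p = 0.0181, adjusted p 0.0241; rho = -0.943, exact p = 0.0167), but r was -0.634 without Yorkshire 3 and Wannanhua 3. The number of peaks rose with filtered tags at r = 0.758 (exact p = 0.0528; rho = 0.657, exact p = 0.175), and r was 0.313 without Yorkshire 3 and Wannanhua 1, so that this relation rests on those libraries. Fragment length separates the breeds, so its 2 relations are not separate from breed. Peak width and fold enrichment also come from the same run of the caller that estimated fragment length. These 2 relations may therefore arise in the calling, and are no evidence on methylation. At nearly equal depth, Yorkshire 2 had 61707 peaks over 38.0 Mb and Wannanhua 3 had 53295 peaks over 39.0 Mb.

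**Figure D2:**
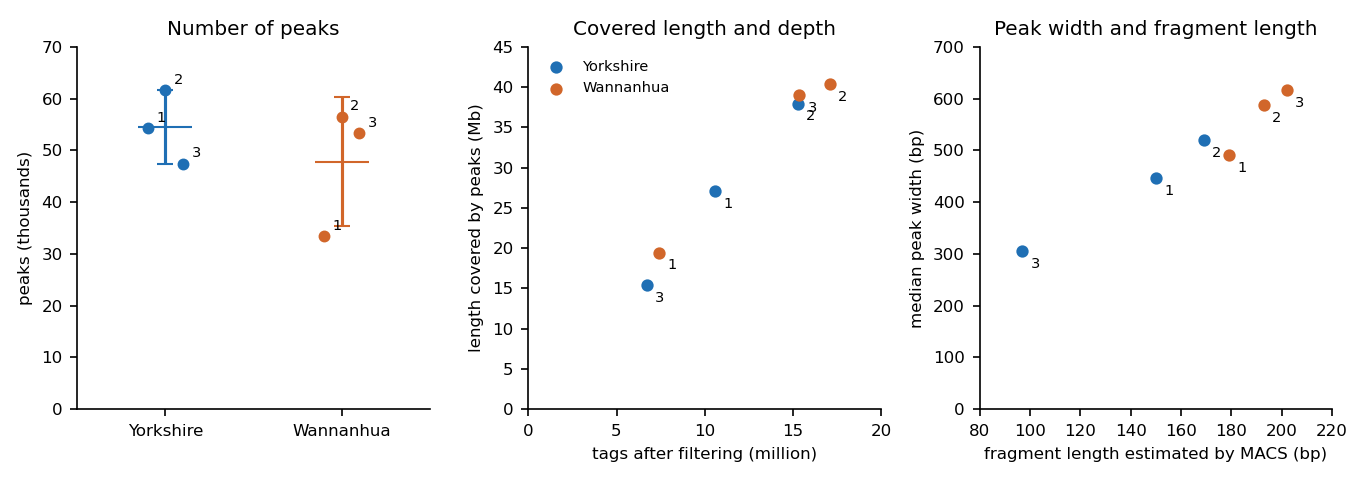
Left, number of peaks per library, with bars for mean ± SD of 3 libraries per breed; middle, length covered by peaks (Mb) against tags after filtering; right, median peak width (bp) against estimated fragment length (bp). Points are libraries, numbered by replicate; covered length follows depth (r = 0.993) and width follows fragment length (r = 0.979).

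A total of 2010 of the 88582 merged regions had a peak in all 3 libraries of one breed and in none of the other, 1303 in Yorkshire only and 707 in Wannanhua only. The Wannanhua-only regions lay towards chromosome ends: 442 of 707 (62.5%) were within 20 Mb of an end, against 545 of 1303 (41.8%) Yorkshire-only regions and 36.7% of all merged regions. These shares pool the chromosomes. Wannanhua-only regions were 1.14% of regions on chromosome 12, where the end zones are most of the length, and 0.64% on chromosome 1. The mix of chromosomes therefore adds to their share near ends, by an amount that was not measured. The Yorkshire-only region with the highest mean score was chromosome 1 from 307338415 to 307341808, with 173, 354 and 134 tags in Yorkshire 1, 2 and 3. Under reciprocal 50% overlap, though, no single region there joined the peaks of all 3 libraries. The Wannanhua-only region with the highest mean score was chromosome 1 from 164267490 to 164268085, with 15, 46 and 46 tags in Wannanhua 1, 2 and 3 and a fold enrichment of 33.2 ± 3.40 (SD, n = 3), and the nearest Yorkshire peak was 13208 bp away.

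Of the 10 named Yorkshire-only regions, 8 were on chromosome 1, and 6 of the 10 stayed so with reciprocal 50% overlap, against 10 of the 10 named for Wannanhua. Besides the region with the highest score, those whose Yorkshire peaks then fell into separate regions were chromosome 1 from 292224986 to 292225451 and from 178611329 to 178611821, and chromosome 12 from 60180319 to 60181598. Narrow and strongly enriched ones were chromosome 1 from 196109671 to 196109984 (25.3 ± 4.04 tags, fold enrichment 34.4 ± 18.2), from 115088466 to 115088940 (fold enrichment 29.3 ± 2.24) and from 292224986 to 292225451 (fold enrichment 31.1 ± 19.2). Outside chromosome 1 were chromosome 11 from 50311893 to 50312321 (fold enrichment 26.8 ± 5.06) and chromosome 12 from 60180319 to 60181598 (fold enrichment 13.5 ± 6.85). The region from 157998480 to 158004811 on chromosome 1 held 910, 2736 and 2574 tags, but a Wannanhua peak began 250 bp further on, in a region from 158005061 to 158011407 with 2723 tags in Yorkshire 3, 3067 in Wannanhua 1 and 4680 in Wannanhua 2 and no peak in the other 3 libraries. Taken as summits with 250 bp on each side, an alternative added after the data were seen, the first of these regions lost its status. No single region there was then called in all 3 Yorkshire libraries and in none of Wannanhua. Of the 10 named Wannanhua-only regions, 4 were on chromosome 10, and 3 were on chromosome 1. They included chromosome 11 from 15691920 to 15692526 (29.3 ± 8.96 tags, fold enrichment 29.9 ± 4.80), chromosome 10 from 73306894 to 73308440 (93.7 ± 24.2 tags) and from 71294401 to 71296036 (103 ± 28.0 tags), and chromosome 13 from 216898031 to 216899702 (84.7 ± 30.2 tags). Chromosome 1 from 206410434 to 206410892 was farthest from a Yorkshire peak, at 20413 bp, while chromosome 13 from 23947918 to 23948338 had a Yorkshire peak 213 bp away.

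By fold enrichment these regions lay below those called in all 6 libraries, and by tags only the Yorkshire-only regions did in every library of their breed. The median fold enrichment in Yorkshire-only regions was 12.3, 10.1 and 19.9 in Yorkshire 1, 2 and 3, below the 18.0, 15.7 and 26.7 of regions called in all 6 libraries. In Wannanhua-only regions it was 11.7, 8.82 and 9.11 in Wannanhua 1, 2 and 3, against 16.2, 14.2 and 13.6. Median tags in Yorkshire-only regions were 15, 20 and 10 against 24, 31 and 17 in regions called in all 6, and in Wannanhua-only regions 15, 31 and 30 against 14, 33 and 30. A peak of the other breed lay within 1 kb of 26.4% of Yorkshire-only and 34.1% of Wannanhua-only regions.

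The direction depended on how many peaks were taken per library. With the 33496 top peaks by score from every library, 937 regions were Yorkshire-only and 1195 Wannanhua-only, so Yorkshire's share fell from 64.8% to 43.9%, and 58.8% of Wannanhua-only and 35.2% of Yorkshire-only regions lay within 20 Mb of an end. Leaving out a library asks for fewer peaks and raised the count, to 3425, 4367 and 4373 without Yorkshire 1, 2 and 3, and to 3914, 4284 and 3538 without Wannanhua 1, 2 and 3; without Wannanhua 1, Yorkshire's share was 39.7%.

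**Figure D3:**
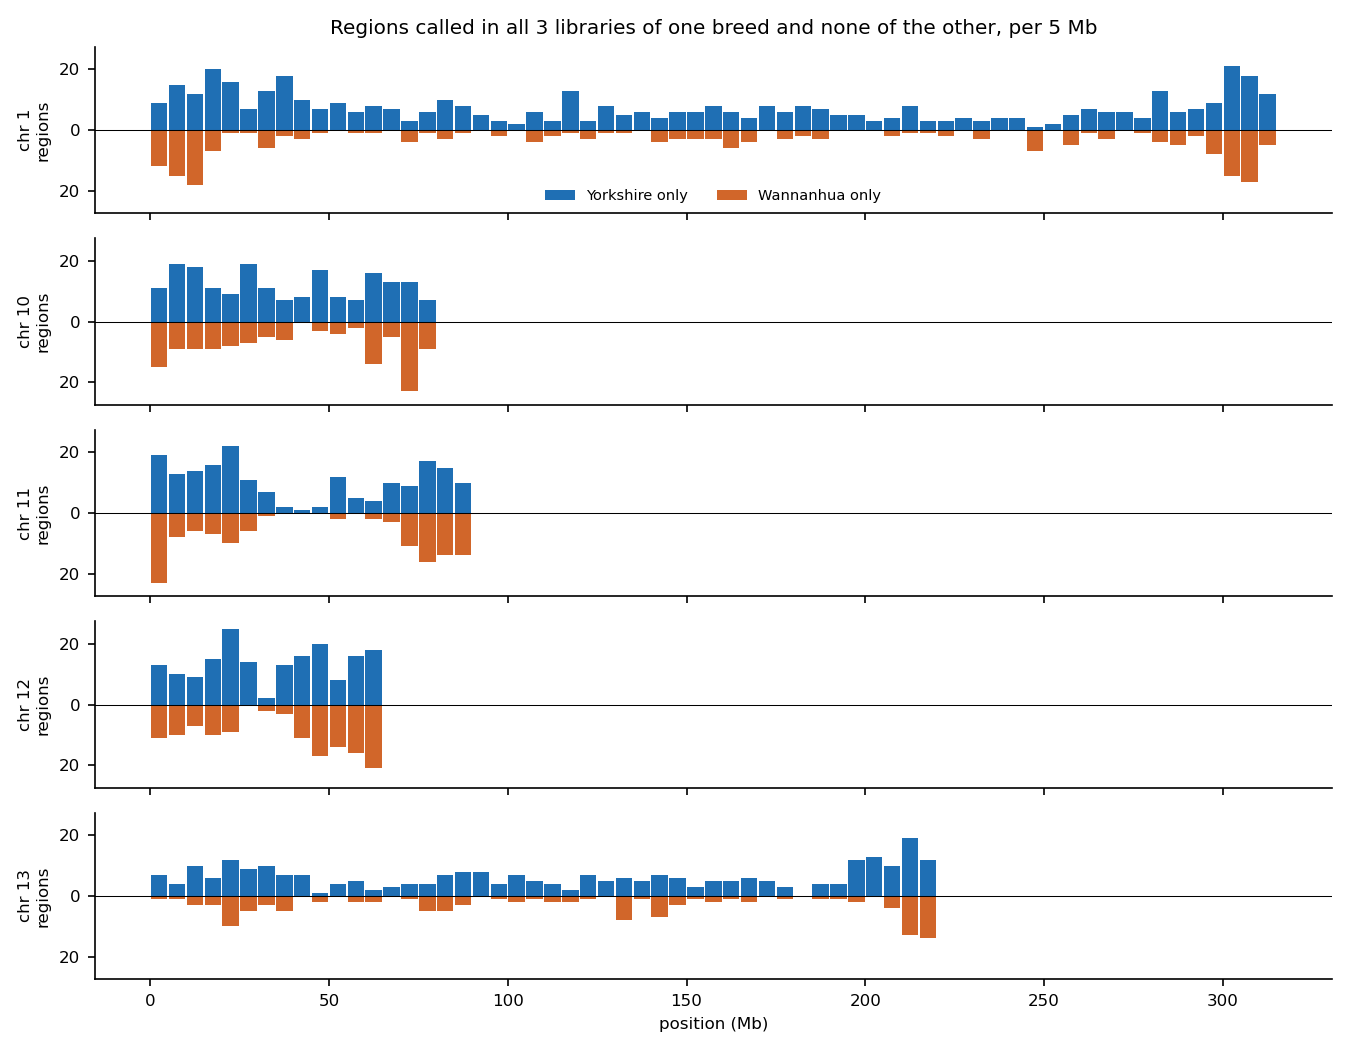
Regions called in all 3 libraries of one breed and none of the other, counted per 5 Mb (vertical axis, number of regions, Yorkshire-only upward and Wannanhua-only downward) along 5 chromosomes (horizontal axis, position in Mb). All peaks are used: 1303 Yorkshire-only and 707 Wannanhua-only regions, the latter mostly near chromosome ends (62.5% within 20 Mb).

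**Figure D4:**
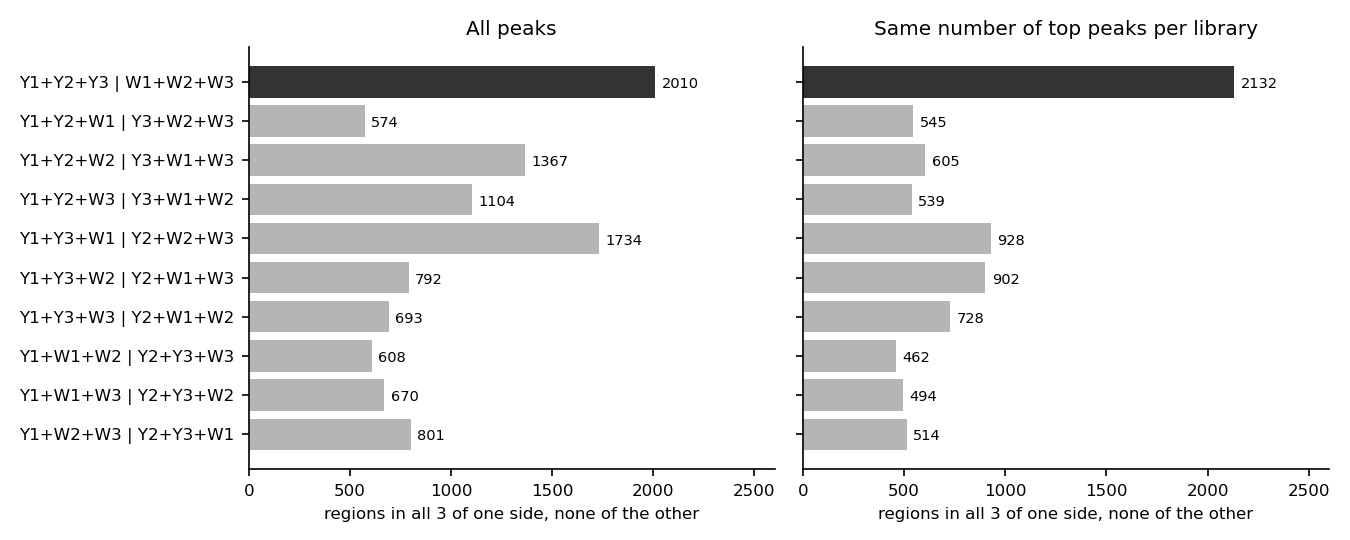
Number of regions called in all 3 libraries of one side and none of the other (horizontal axis) for the 10 splits of the 6 libraries, with Y for Yorkshire, W for Wannanhua and the replicate number; the dark bar is the split by breed. Left, all peaks (2010 by breed, at most 1734 otherwise); right, the same number of top peaks from every library (2132 by breed, at most 928 otherwise).

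In the 19161 regions called in all 6 libraries, 104 had more tags in Wannanhua and 29 more in Yorkshire by edgeR's quasi-likelihood test at an adjusted p of 0.05. The 104 were wide, with a median of 1543 bp against 772 bp in regions that did not pass, and 72 of them (69.2%) lay within 20 Mb of a chromosome end, against 30.3% of the regions tested. Of the 104, 25 were on chromosome 12, which held 2064 of the regions tested, so the mix of chromosomes adds to this share too. The 29 had a median width of 693 bp, and 11 of them (37.9%) lay near an end. The median log2 fold change of Wannanhua over Yorkshire was 1.41 among the 104 and -1.16 among the 29.

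The calls of single regions depended on single libraries: of the 20 named here, 10 per direction, 0, 20 and 15 kept an adjusted p under 0.05 without Yorkshire 1, 2 and 3, and 11, 0 and 1 without Wannanhua 1, 2 and 3. With alternatives added after the data were seen, 1 kept it with fragment length as a covariate and 3 with called length as an offset.

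All 10 named regions with more tags in Wannanhua lay within 20 Mb of a chromosome end, which on chromosome 12 takes in most of the length. Chromosome 12 from 48761022 to 48762901 had 69.4 ± 50.3 CPM in Yorkshire and 458 ± 68.8 CPM in Wannanhua (SD, n = 3, TMM-scaled over tags in the tested regions), a log2 fold change of 2.67 with SE 0.50 (edgeR adjusted p = 0.0122, but 0.120 without Yorkshire 1). Peaks called there covered on average 1005 bp in Yorkshire and 1495 bp in Wannanhua, so that CPM per kb of called peak were 75.9 ± 17.7 and 316 ± 56.8. Chromosome 1 from 307539513 to 307545051 had a log2 fold change of 2.42 with SE 0.46 (edgeR adjusted p = 0.0135), but peaks covered 708 bp in Yorkshire and 3769 bp in Wannanhua, and CPM per kb were 101 ± 11.7 and 108 ± 39.9. Chromosome 12 from 63125716 to 63133360 had a log2 fold change of 2.34 with SE 0.47, with 1440 and 5978 bp called. Further named regions were chromosome 13 from 218015066 to 218018859 (2.25), chromosome 1 from 310482799 to 310486718 (2.23), from 1087761 to 1090106 (2.20), from 305433994 to 305437355 (2.08) and from 2242783 to 2246318 (2.07), and chromosome 12 from 1665860 to 1671277 (2.10) and from 1222505 to 1224902 (2.07), all as log2 fold changes. Per kb of called peak, the fold of Wannanhua over Yorkshire in the 10 regions had a median of 1.17 and ran from 0.92 to 4.16, where the median of all 19161 regions was 0.755. It was above 1 in 8 of the 10. On chromosome 12 from 1665860 to 1671277 it was 0.985, with 1412 bp called in Yorkshire and 5339 bp in Wannanhua. On chromosome 1 from 2242783 to 2246318 it was 0.924, with 668 and 3018 bp called.

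The 10 named regions with more tags in Yorkshire had called lengths that differed less between the breeds, and per kb the fold of Wannanhua over Yorkshire had a median of 0.469 and ran from 0.342 to 0.595. Relative to the median of all regions these folds were 1.56 in the Wannanhua set and 0.621 in the Yorkshire set. Chromosome 12 from 28504955 to 28505656 had 119 ± 22.1 CPM in Yorkshire and 38.7 ± 10.5 in Wannanhua, a log2 fold change of -1.63 with SE 0.32 (edgeR adjusted p = 0.0183), with 525 and 467 bp called. Chromosome 1 from 294488263 to 294488974 had a log2 fold change of -1.51 with SE 0.31, with 508 and 495 bp called. Chromosome 1 from 10893560 to 10894210 (-1.47) and from 4936574 to 4937266 (-1.36), and chromosome 11 from 73887058 to 73887689 (-1.46), followed, and the smallest of the 10 was chromosome 12 from 12133736 to 12134620 (-1.24).

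The count of regions that passed depended on single libraries. The count of 133 became 1, 1864 and 67 without Yorkshire 1, 2 and 3, and 53, 6 and 12 without Wannanhua 1, 2 and 3. With fragment length as a covariate 6 regions passed (2 higher in Wannanhua and 4 in Yorkshire), of which 2 were among the 133. In that fit the median log2 fold change of the 133 went from 1.31 to 1.13. The median SE of single regions went from 0.30 to 0.44. With called length as an offset 10 passed (1 higher in Wannanhua and 9 in Yorkshire), 3 of them among the 133. DESeq2 passed 510 (488 higher in Wannanhua), 72 of them among the 133, and gave no adjusted p for 14859 regions. With scaling by library size alone, 104 were higher in Wannanhua and 87 in Yorkshire, a share of 54.5% in place of 78.2%, and the median log2 fold change of all regions moved from -0.04 to -0.16.

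Tags in shared regions set Yorkshire 3 apart, the library with the shortest fragments and the highest rate of redundant tags (0.69). The mean Pearson correlation of log2 tags was 0.724 within breeds and 0.617 between them, and the difference, 0.107, was larger than in the other 9 splits of the libraries, whose highest was 0.046. By this measure Wannanhua libraries resembled each other (mean 0.833) more than Yorkshire libraries did (mean 0.614). Yorkshire 2 correlated at 0.759, 0.824 and 0.813 with Wannanhua 1, 2 and 3, but at 0.703 with Yorkshire 1 and 0.512 with Yorkshire 3. The first principal component, with 51.5% of the variance, placed Yorkshire 3 at 0.72, Yorkshire 1 at 0.38, Yorkshire 2 at -0.09 and the Wannanhua libraries between -0.34 and -0.32. For the presence of peaks, with the same number of top peaks from every library, the mean Jaccard index was 0.533 within breeds and 0.481 between them, a difference of 0.052 against at most 0.011 in the other splits. By presence the order of the breeds turned, with a mean Jaccard index of 0.541 in Yorkshire pairs and 0.525 in Wannanhua pairs, and 0.569 and 0.528 with all peaks. These are correlations across regions, which are not independent replicates.

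**Figure D5:**
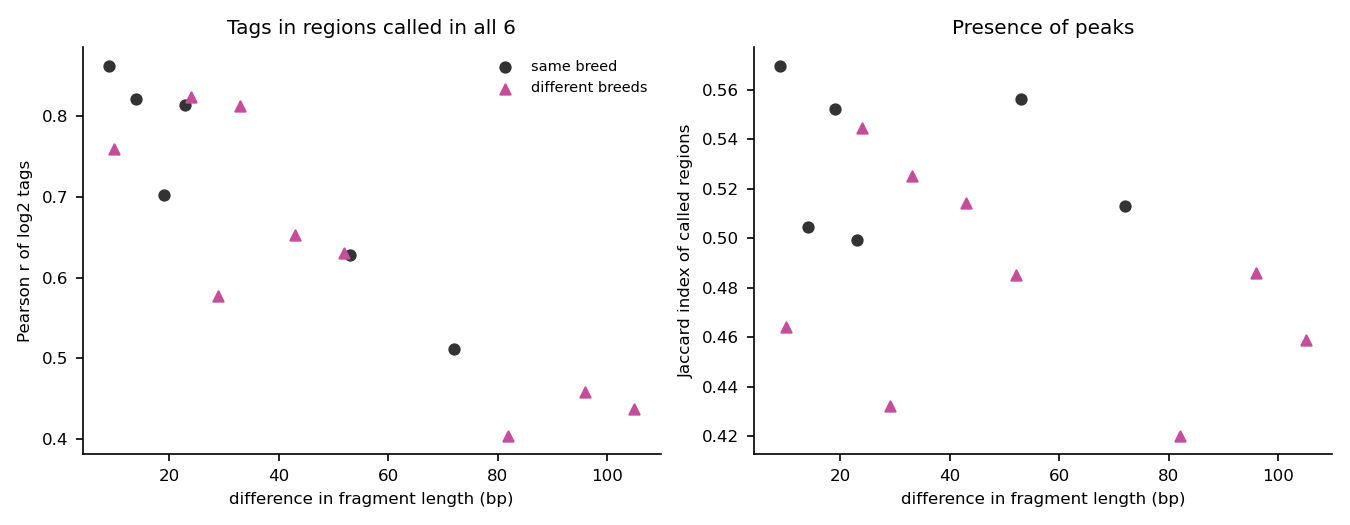
Similarity of the 15 pairs of libraries against their difference in estimated fragment length (bp), for same-breed pairs (circles) and pairs of different breeds (triangles). Left, Pearson's r of log2 tags in the regions called in all 6 libraries; right, Jaccard index of called regions with the same number of top peaks from every library. The left axis starts at about 0.4 and the right axis at about 0.42; mean r is 0.724 within and 0.617 between breeds.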

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

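Tests chosen after the result was seen are the splits of the test of tags, the bound on the share of splits, the test of fragment length on tags, the fits with fragment length as a covariate and on regions with 1 peak per library alone, the called lengths by direction (with bounds restated relative to all regions once the values were known), and the bound for equal numbers of peaks, a setting planned beforehand. The splits for regions in a single breed and for similarity were planned beforehand. The tests on the rate of calls in regions with 1 peak per library, on fragment length in pairs of libraries and on local density were written before their results were seen.

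Peaks outside the 5 chromosomes that all lists cover in full were used in no comparison of breeds, apart from the start of chromosome 14. There were 11192 in Yorkshire 1, 3809 in Yorkshire 2, 18070 in Yorkshire 3, 32020 in Wannanhua 1, 8982 in Wannanhua 2 and 12221 in Wannanhua 3. These numbers follow from where each list stops, since every list holds 65516 peaks, and they carry no breed comparison.

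The 104 regions with more tags in Wannanhua and the 29 with more in Yorkshire were weighed against the grouping, fragment length and the extent of called peaks. Of the 10 splits of the libraries 1, the real one, gave as many as 133 calls and the highest other gave 1, but 10 splits are too few for a share under 0.05. Called length was a median 2.48 times as long in Wannanhua in the 104 and 0.931 times in the 29, which relative to all tested regions is 1.96 beside a fold in tags of 2.66, consistent with wider called peaks as a main part, and 0.737 beside 0.448, which decides nothing; per kb of called peak both sets still lay apart from all regions (1.55 and 0.622 times), as selection for a difference in tags would also give. The test written beforehand, on all 133, gave 5.72 calls per 1000 in regions with 1 peak in every library and 18.4 in the others. That ratio, 0.311, is the outcome predicted for called extent as a source. The ratio cannot decide, since regions with several peaks may also hold more tags, and more tags make a call easier. Of the 133, 109 were called when only the 9681 regions at or above the median of mean tags were tested. Of the 133, 99 lie in regions with 1 peak in every library, as do 17313 of the 19161 tested. Tested alone, these regions gave 176 calls (141 and 35). Several peaks per region are therefore not needed for a call. Stronger methylation may itself widen a peak, but width also went with the fragment length that the caller estimated. Fragment length and breed cannot be told apart. The slope on fragment length within breeds had the sign of the breed difference in 78.9% of the 133, against 65.0% of all tested regions. The exact binomial 95% interval of that 78.9% was 71.0 to 85.5, but it takes regions as independent. All regions come from the same 6 libraries, so the interval does not measure the spread between libraries. Within Yorkshire, fragment length also ran in the order of depth, so the slope is not separate from depth. It predicts a median log2 change of 0.31 (median SE of single regions 0.39) against 1.31 observed. Beside fragment length the median was 1.13, and the median SE of single regions rose from 0.30 to 0.44. What ended the calls was not tested separately, and a methylation difference between the breeds stays open.

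The 2010 regions called in a single breed were weighed against the grouping, the number of peaks and fragment length. As deposited, 1 of the 10 splits, the real one, gave as many, and the highest other, 1734, parted Yorkshire 2, Wannanhua 2 and Wannanhua 3, the deepest libraries, from the rest. With the planned reciprocal 50% overlap that other split gave 2522, above the 2110 by breed. In any case 10 splits are too few for a share under 0.05. Unequal numbers of peaks as the whole source are argued against, since with equal numbers the breeds gave 2132, which is 2.30 times the highest other split, although which breed had more regions turned with that setting. In 80% of the 15 combinations where a same-breed pair differed more in fragment length than a pair of different breeds, the same-breed pair still shared more regions, which does not pass the bound of over 80% set beforehand; it was 53.3% with all peaks as deposited and 20% with tags in place of presence. Fragment length, other preparation differences and the breeds' own methylation or sequence therefore cannot be told apart here.

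Regions called in Wannanhua only lay close together, with 71 neighbours within 50 kb against a mean of 50.6 in random draws from regions called in 3 libraries (permutation p = 0.0023), while Yorkshire-only regions had 153 against 147. Some groups of 3 libraries that mix the breeds had higher ratios, such as Yorkshire 1, Yorkshire 3 and Wannanhua 2 with 36 against 22.8. Against draws matched to 5 Mb windows the Wannanhua number was 0.976 times the mean of 72.7, so local density on the scale of these windows may be the source, and no clustering beyond it was detectable. Why Wannanhua-only regions lie in such windows was not tested.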

How the results depend on the processing

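Alternatives added after the data were seen are named as added; the cause of a change was not tested unless stated. The count of regions with a breed difference in tags, 133, became 273 with a replicate block, 510 with DESeq2 (14859 of its adjusted p-values were NA) and 455 at an adjusted p under 0.1. They ranged from 1 to 1864 with each library left out, which also lowers the number of samples. Added alternatives gave 6 with fragment length as a covariate, 10 with called length as an offset, 256 with whole-library tags as library size and 32 without Yorkshire 3 and Wannanhua 1. Other scalings, filters, a log2 fold change above 1, regions with 1 peak per library and the part of chromosome 14 kept it within 1.5 times, from 133 to 191. No pairing of samples by replicate number was detectable, as deviations of same-numbered libraries correlated at -0.01, 0.03 and -0.05. With 3 libraries per breed this cannot exclude a pairing or a shared batch. The named region on chromosome 1 from 2242783 to 2246318 turned to -0.083 with called length as an offset. The 2010 regions in a single breed ranged from 3425 to 4373 with each library left out, where fewer peaks are asked for, and were 6851 without Yorkshire 3 and Wannanhua 1, or 5283 with equal numbers of peaks too. Other overlaps and equal numbers kept them within 1.5 times (2110 to 2212), but with reciprocal overlap another split gave 2522. The Yorkshire share of 64.8% turned to 43.9% with equal numbers of top peaks, 44.1% with these at summits and 47.8% with these without Yorkshire 3 and Wannanhua 1, and ranged from 39.7% to 77.9% with each library left out. With peaks of at least 400 bp, Wannanhua minus Yorkshire turned to 11127 peaks per library and 2.57 tags in peaks per 100; this follows from its wider peaks. With each library left out these ranged from -11097 to 422 and from -1.13 to 0.37. The difference in CPM per peak, 0.21, was -0.056 with the median and from 0.034 (without Wannanhua 1) to 0.337 with each library left out. Width (82.0 to 190 bp with each library left out), end-to-interior ratio (0.050 to 0.157) and similarity kept their direction under every alternative run. Of all alternatives to comparisons 56 kept their direction within the limit for their kind of value (1.5 times for counts and 1 SD for library values), 23 moved further and 9 turned; of those to named regions 345 kept the call or value, 118 lost the call, 6 moved and 1 turned. Named regions in a single breed stay so by construction when a library is left out. Gene lists, coverage, pseudocount and sex chromosome alternatives were not run. Depth limits the absence of a peak most in Yorkshire 3 and Wannanhua 1.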

Other observations

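The tests in this part were chosen after the data had been seen. The location of regions went with fragment length within breeds as well as with breed. Within Yorkshire, fragment length (97, 150 and 169 bp in Yorkshire 3, 1 and 2) ran in the order of filtered tags (6728444, 10600292 and 15275918). Within Wannanhua it ran only from 179 to 202 bp. Depth is therefore not separate from fragment length here. In a model with breed, edgeR called 86 shared regions with more tags in libraries with longer fragments and 3 with fewer. Of the 86, 63 (73.3%) lay within 20 Mb of a chromosome end, against 69.2% of the 104 regions with more tags in Wannanhua, 37.9% of the 29 with more in Yorkshire and 30.3% of all regions tested. Among groups of 3 libraries that mix the breeds, the share of regions found in those 3 alone that lay near an end ran from 32.0% to 57.9%, below the 62.5% of Wannanhua. With the same number of top peaks it ran from 24.8% to 54.2%, below the 58.8% of Wannanhua.

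Of 18 regions with at least 1000 tags in some library, 7 were called in all 6 libraries and 11 were missing in at least 1. Chromosome 10 from 15773704 to 15785994 held 5364 tags in Yorkshire 1 and 6825 in Yorkshire 3 and was not called in the other libraries. Chromosome 12 from 53588330 to 53595682 was called in Yorkshire 3 alone, with 3779 tags. Tags outside called peaks are not listed, so libraries without a call may hold tags there too. Chromosome 12 from 61817059 to 61825864 was called in all 6, with 2674 to 5427 tags. These regions were chosen by size after their values were seen.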
